A study of Drosophila melanogaster with 10 samples.

How the data were processed

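Expression was measured in Drosophila melanogaster embryos with Affymetrix DrosGenome1 arrays, 1 array per embryo collection and 10 in all. The values are the signal intensity per probe set that the authors deposited, on a linear scale with 1 colour, made with MAS5 per the submitters' processing notes; its version and its detection calls were not given in the sources used here. From the values themselves, each array's mean, trimmed by 2% at each end, is 250.04, so that the deposited intensity was globally scaled by the authors. MAS5 signal combines matched and mismatched probes, and low values are noisy. The run records of the arrays were used only to find which arrays were run together. They fall on 3 hybridization days, each with a chip batch of its own. The day 1 arrays (yw) also had a fluidics protocol of their own. Groups, strains and sets were taken from the sample labels, and per the labels' protocols the control and irradiated collections differed only in the radiation. The series describes the arrays as paired sets and as biological replicates.

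The table holds 14010 probe sets, of which 44 Affymetrix controls were left out of all tests. Gene symbols came from the platform annotation: 12442 probe sets had 1 symbol, 327 had several and 1197 had none here, and a probe set with several symbols was not named. Of the Entrez gene identifiers 12393 matched the Release 6 gene table, which changed 0 symbols; no genome coordinates are given, since the build behind the array was not stated. rpr, hid, Xrp1 and w have no named probe set here and were not analysed. Arrays were rescaled to a common trimmed mean, which moved them by almost nothing. Values were analysed as log2(signal + 14.5), where 14.5 is the 20th percentile of all values, so that fold changes of dim probe sets are understated. Probe sets with a mean signal above 53.36 (the 40th percentile) were kept, which left 8379 probe sets and 6848 genes; 503 genes had several, and the one with the highest mean signal stands for the gene, with the others given where they differ in a call.

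The irradiation effects of WT and mutant embryos and their difference were fitted to all 10 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), with each control and irradiated set as a fixed block, leaving 3 residual degrees of freedom beside 18.1 prior ones. The pairing comes from the series' own description. The deviations of control and irradiated arrays from their group means correlated across probe sets within every set, at 0.639 (yw), 0.652 and 0.584 (w1118) and 0.428 (mutant). The WT values also hold the difference between yw and w1118 and all hold that between hybridization days, so they do not check the pairing. Both mutant sets give the same value by construction. Mutant against WT (the mean of yw and w1118) and yw against w1118 were fitted with strain and irradiation terms and set as a random block (consensus correlation 0.2, 5 residual and 5.72 prior degrees of freedom). Adjusted p-values are Benjamini-Hochberg values over the probe sets kept, two-sided, with a threshold of 0.05. Gene lists with at least 3 measured members (25 lists) were tested with limma's camera, with a preset correlation of 0.01 and again with an estimated one, and with fry; for the strain comparisons these list tests treat the arrays of a set as independent. Camera compares a list with all other probe sets, so its direction can differ from the sign of a median. The tests, the gene lists, the filter, the alternatives and the rule for named genes were fixed before the data were examined. That rule takes, among probe sets with 1 symbol past 0.05 and changed the same way in every set, the 15 largest rises and 10 largest falls for WT irradiation and the 10 and 10 largest for other contrasts, members of the lists that passed in any contrast, and a short list of radiation-response genes plus w and y whether or not they passed. The 4 unnamed probe sets called in WT embryos, and list members given only as passing within their list, were named after their values were seen.

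The fits were tested on simulated data with the real probe sets and arrays. For WT irradiation over 8379 probe sets, 46% of changes of 1 log2 and 98% of changes of 2 log2 were recovered, with 4.89% of calls false. At an unadjusted p under 0.05, camera called 5 of 100 unchanged lists and 100 of 100 shifted ones. The simulated genes were independent of each other, so this does not check camera's preset correlation or its calls on lists of correlated genes. For mutant against WT, 73.7% of differences of 2 log2 were recovered and 6.36% of calls were false. Noise was drawn as normal, with the fitted spread of each probe set shared by WT and mutant arrays. The simulated rates, also those given below for the difference between genotypes, may therefore be better than on the real data. Alternatives covered the scaling, the pseudocount, the filter, the variance model, the threshold, the block, the arrays in the fit, a 1.5-fold rule with no test, the list tests and leaving out each of the 5 sets. An irradiation term per hybridization day, and mutant against w1118 within days, were added after the data were seen. The comparison within days had day terms and no set block, so it treated the arrays of a set as independent. Neither draws on the yw set, since no mutant set shares its day. Random lists for comparison were drawn 10000 times, matched on mean signal. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.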

Results

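Gene expression was measured in whole Drosophila melanogaster embryos to ask which transcripts respond to ionizing radiation through Dmp53, the fly p53 transcription factor. Embryos gathered over the 0 to 2.5 h that followed egg laying were aged for another 2.5 h, received 40 Gy or a mock treatment, and were harvested after 1.5 h of recovery. Total RNA of each collection was hybridized to 1 single-colour Affymetrix Drosophila genome array. Wild-type (WT) embryos came from the yw strain (1 set of a control and an irradiated array) and the w1118 strain (2 sets). Mutant embryos came from the Dmp53NS strain (2 sets). There were thus 3 WT control, 3 WT irradiated, 2 mutant control and 2 mutant irradiated arrays, and their number limits the precision of every value below. The yw set was hybridized alone on day 1, and each of days 2 and 3 held 1 w1118 set and 1 mutant set. Median signal per array was 63.2 to 108 in the arbitrary units of the deposited values. On the yw arrays 15.97% and 16.9% of probe sets had a signal under 20, against 24.0% to 30.04% on the others. The 3′ to 5′ signal ratio of the eIF-4a control probe sets was 12.2 on the irradiated array of the second w1118 set and 5.92 on the control array of the second mutant set, and lay between 1.56 and 3.13 elsewhere. The 18S rRNA probe set read 1939 and 1290 on the yw arrays and 3.4 to 493 on the others. Log2 signals of arrays of the same group correlated across probe sets at 0.885 to 0.905 within a strain and at 0.80 to 0.836 between yw and w1118.

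The p53 probe set (150416_at) gave a signal in both genotypes. Its signal in WT controls was 243 (yw), 233 and 288 (w1118), and in irradiated WT embryos 505, 499 and 261. In the mutant it was 194 and 125 without and 213 and 104 with irradiation. Neither the WT change of 0.64 log2 (SE 0.29, adjusted p = 0.59) nor the difference of -0.69 log2 between unirradiated mutant and WT embryos (SE 0.41, adjusted p = 0.285) passed the test. The position of this probe set relative to the mutated part of the gene was not given in the sources used here, so its signal checks nothing about the genotype labels.

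The comparison of irradiated with control WT embryos asked which transcripts respond to radiation when p53 is intact. Genes on the fixed list of apoptosis effectors, skl, Corp and egr, were among the strongest responders. Corp is counted there by the list, and its role in cell death was not tested. The proapoptotic gene skl (148994_at) rose 8.79-fold, from a signal of 71.4 ± 40.7 to 796 ± 479 (SD, n = 3 each; log2 change 3.14, SE 0.45, adjusted p = 8.47e-04). Corp (153035_at) rose 4.16-fold, from 484 ± 86.0 to 2057 ± 313 (log2 change 2.06, SE 0.24, adjusted p = 4.91e-05), and egr (146921_at), which encodes the fly tumour necrosis factor, rose 3.08-fold, from 123 ± 42.3 to 398 ± 67.3 (log2 change 1.62, SE 0.31, adjusted p = 0.0160). RnrL, the large subunit of ribonucleotide reductase, which supplies deoxynucleotides, rose 2.19-fold, from 668 ± 332 to 1482 ± 757 (log2 change 1.13, SE 0.22, adjusted p = 0.0187). The largest change belonged to a probe set with no gene name here, 141483_at, which rose 20.7-fold, from 56.6 ± 44.7 to 1320 ± 420 (log2 change 4.37, SE 0.39, adjusted p = 2.18e-06). In all, limma called 20 of 8379 probe sets, and all 20 rose in each of the 3 WT sets. The median change of these 20 was 2.07 log2 in the yw set, 1.31 in the first w1118 set and 1.62 in the second, each on its own hybridization day. The other named genes that rose were CG10916 (2.42 log2), CG12194 (2.30), CG12171 (1.97), the kinase gene Wnk (1.89), IscU (1.73) and bcn92 (1.33) of iron-sulphur cluster assembly. They also included the Polycomb group gene escl (1.72), the mitochondrial copper chaperone gene Cox17 (1.52), Irbp18 (1.52), which encodes a bZIP protein, rdog (1.50), CG18596 (1.40) and CG15480 (1.20). The remaining unnamed ones were 143680_at (2.56), 143411_at (1.62) and 143721_at (1.20). No probe set passed as lower, and 683 had an unadjusted p under 0.05 where 419 would be expected by chance. Of the genes always reported, mre11 (1.06 log2, adjusted p = 0.130), Ku80 (1.09, adjusted p = 0.349), Irbp (0.92, adjusted p = 0.415), Dark (0.59, adjusted p = 0.628) and y (0.20, adjusted p = 0.970) did not pass. The count was 32 without the yw set, 41 without the first w1118 set, 12 without the second w1118 set, and 12 without either mutant set, which shares the estimate of the spread. Only 141483_at, 143411_at, 143680_at, CG10916, CG12194, Corp, escl and IscU (8 of the 20) passed without each of the 5 sets in turn. The calls lost numbered 7 without the yw set, 2 without the first and 9 without the second w1118 set, and 8 without the first and 8 without the second mutant set. The size of the rise of skl moved too, from 4.94 log2 in the yw set to 3.03 and 1.44 in the w1118 sets, with a fitted change of 2.23 without the yw set and 3.98 without the second w1118 set. Without the yw set the changes of 141483_at, CG10916 and CG12171 were 3.72, 1.82 and 1.21 log2, and that of 141483_at was 3.76 with a higher pseudocount. The call of skl was lost without the first or second mutant set (adjusted p = 0.102 and 0.10003). That of egr was lost without the first or second w1118 set (0.0655 and 0.266) or the first or second mutant set (0.108 and 0.126). RnrL did not pass without the yw set (0.0733) or the first or second w1118 set (0.0523 and 0.1397). The count was 12 with quantile normalization, 8 with no filter on dim probe sets, 34 with a stricter one, 3 without a variance trend, 11 with WT arrays alone, and 5 with no set block or 6 with a random one.

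**Figure D1:**
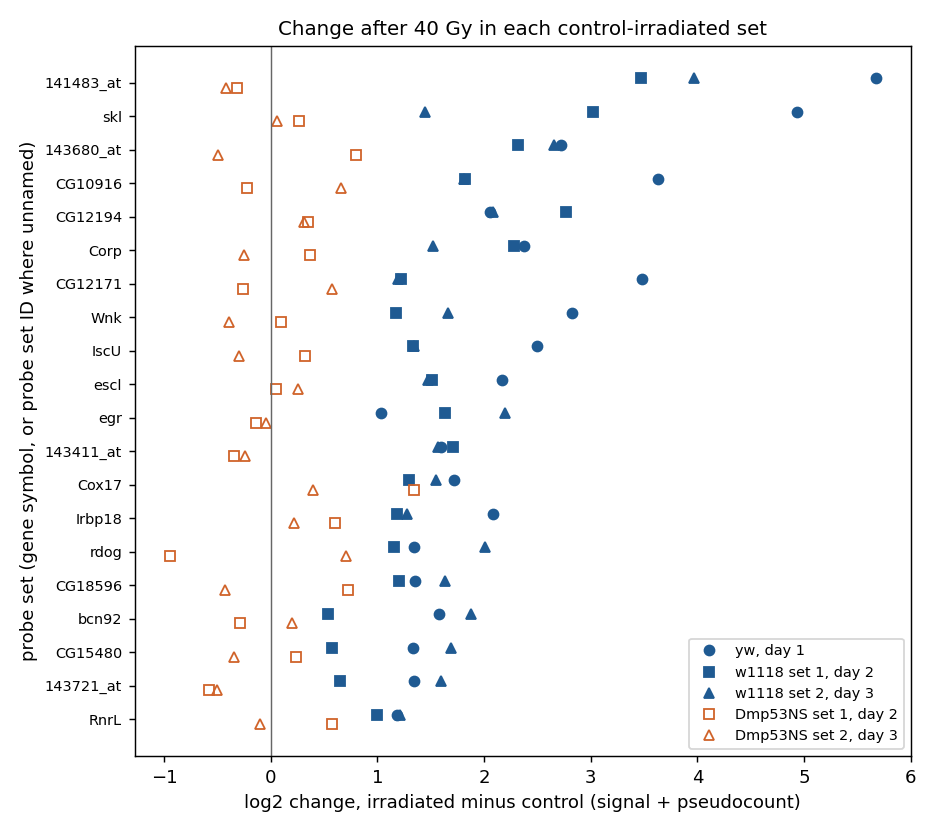
Log2 change after 40 Gy (irradiated minus control, signal plus pseudocount) of the 20 probe sets called in WT embryos, with 1 point per control and irradiated set; filled blue points are WT sets and open orange points are Dmp53NS sets. Every WT point lies above 0, and the largest change fitted for the mutant is the 0.87 log2 of Cox17.

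Grouped by function, the lists of apoptosis effectors and DNA repair genes had positive median changes in irradiated WT embryos. Of 9 measured genes on the apoptosis effector list 3 rose (skl, egr and Corp), and 3 did when adjusted over the list alone. The median change of the list was 0.23 log2 (camera adjusted p = 1.45e-04, but adjusted p = 0.247 with an estimated correlation). None of 14 genes of DNA double-strand break repair passed over all probe sets, while 5 did when adjusted over the list alone: Irbp and Ku80, the Ku heterodimer that binds broken ends, mre11 and rad50 of the end-processing complex, and the ligase gene DNAlig4. Their changes were 0.92, 1.09, 1.06, 1.23 and 1.42 log2, of which that of DNAlig4 was 3.01 in the yw set but 1.31 and -0.07 in the w1118 sets. The list had a median of 0.35 (camera adjusted p = 7.84e-04; adjusted p = 0.306 with an estimated correlation). Of 11 other DNA repair genes 0 passed limma over all probe sets, and 2 passed adjusted over the list alone, the translesion polymerase gene PolZ1 (1.35 log2) and the damage recognition gene Xpc (0.89). The median of that list was 0.28 log2 (camera adjusted p = 0.0139; adjusted p = 0.338 with an estimated correlation). Of 10 checkpoint and nucleotide supply genes RnrL rose, RPA2 (0.63 log2) joined it when adjusted over the list alone, and the median was 0.24 log2 (camera adjusted p = 0.00493; adjusted p = 0.541 with an estimated correlation). Among 8 measured genes published as radiation targets of p53, skl, egr, Corp and RnrL rose, 7 passed adjusted over the list alone, and the median was 1.11 log2 (camera adjusted p = 1.05e-17; adjusted p = 0.138 with an estimated correlation). That list is not independent evidence, because the study itself may have chosen its genes on these samples. It shares skl, egr, Corp and Dark with the apoptosis effectors, Irbp, Ku80 and mre11 with double-strand break repair, and RnrL with the checkpoint list. All 8 of its measured genes are thus also on those lists. Those lists are therefore not fully separate evidence. In the opposite direction, 7 genes of trachea, salivary gland and epidermis had a median of -0.44 log2 (camera adjusted p = 0.0102; adjusted p = 0.653 with an estimated correlation). None of those 7 passed over all probe sets, and vvl (-0.85) and kni (-1.07), which encode transcription factors, were lower when adjusted over the list alone. Without the yw set, camera no longer called the other DNA repair (adjusted p = 0.0624), checkpoint (adjusted p = 0.0998) and trachea, salivary gland and epidermis lists (adjusted p = 0.0565).

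The remaining lists did not pass camera in irradiated WT embryos. Their median log2 changes were 0.02 for 27 cell cycle and mitosis genes (mean -0.02), -0.09 for 9 heat shock and chaperone genes, 0.07 for 17 genes of oxidative stress and detoxification, -0.09 for 12 JNK pathway genes, 0.20 for 6 immune response genes and 0.21 for 4 JAK-STAT genes. Among developmental groups they were 0.07 for 14 maternal transcripts, -0.11 for 19 cellular blastoderm genes, -0.10 for 15 later patterning and neurogenesis genes, -0.22 for 7 mesoderm genes, -0.11 for 6 endoderm and yolk genes and -0.23 for 11 amnioserosa and dorsal ectoderm genes. They were -0.01 for 7 germ line genes (mean 0.23), 0.17 for 7 hemocyte genes, -0.22 for 6 late differentiation genes, -0.28 for 6 genes of adult ovary or chorion and -0.47 for 4 sex and dosage compensation genes. The 13 ribosomal protein genes had a median of -0.06 (0.02 with quantile normalization), and the 3 housekeeping genes -0.16. Camera's adjusted p was 0.198 or more for each of these lists, and the 2 measured apoptosis inhibitors, with a median of 0.24, were too few to test. Adjusted over the list alone, GstD1 (0.66 log2), GstD5 (1.29) and GstE6 (1.21) of detoxification, tud (1.22), halo (0.93) and dpp (1.09) were higher, and cad (-1.21) and Doc1 (-0.65) lower. The yw set carried most of the change of cad (-2.91 log2, against -0.28 and -0.45 in w1118) and of dpp (2.15, against 0.13 and 0.99). Without the second w1118 set camera called the ribosomal proteins as lower (adjusted p = 0.0175).

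The comparison of irradiated with control mutant embryos asked which transcripts respond when p53 is defective. None of the genes on the apoptosis effector list that rose in WT embryos passed here. Corp went from a mean signal of 387 to 397 (n = 2 each, 0.06 log2, 95% interval -0.55 to 0.67). The signal of skl went from 41.5 to 50.8 (0.16 log2, -0.99 to 1.31) and that of egr from 122 to 113 (-0.09 log2, -0.87 to 0.69). The DNA end-binding genes Ku80 (1.44 and -0.36 log2) and Irbp (0.80 and 0.49 log2) are given per mutant set, the first on day 2 and the second on day 3. Over the 20 probe sets called in WT embryos the median change was 0.11 log2 in the mutant against 1.67 in WT, and 12 of the 20 were higher. Within days it was 0.17 log2 in the first mutant set and -0.07 in the second. The largest of the 20 was Cox17 at 0.87 log2 (95% interval 0.18 to 1.56). These probe sets were chosen on the WT arrays, which inflates their WT changes. Limma called 0 probe sets, and 134 had an unadjusted p under 0.05 where 419 would be expected by chance. A number under that expected does not show that mutant embryos lack a response. The changes of the 2 mutant sets ran against each other (correlation across probe sets -0.29), so that their mean can hide changes. Limma's count was 3, all lower, without the yw set and 1 with mutant arrays alone. Camera called 2 lists as lower: 15 later patterning and neurogenesis genes, with a median of -0.21 log2 (adjusted p = 0.0165; adjusted p = 0.985 with an estimated correlation), and 6 late differentiation genes, with a median of -0.32 (adjusted p = 0.0165; adjusted p = 0.985 with an estimated correlation). The medians per set were 0.21 on day 2 and -0.66 on day 3 for the first list and -0.07 and -0.43 for the second. Without the first mutant set camera called 5 lists, with late differentiation no longer among them (adjusted p = 0.130), and without the second it called 0 (adjusted p = 0.738 for later patterning and 0.436 for late differentiation).

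**Figure D2:**
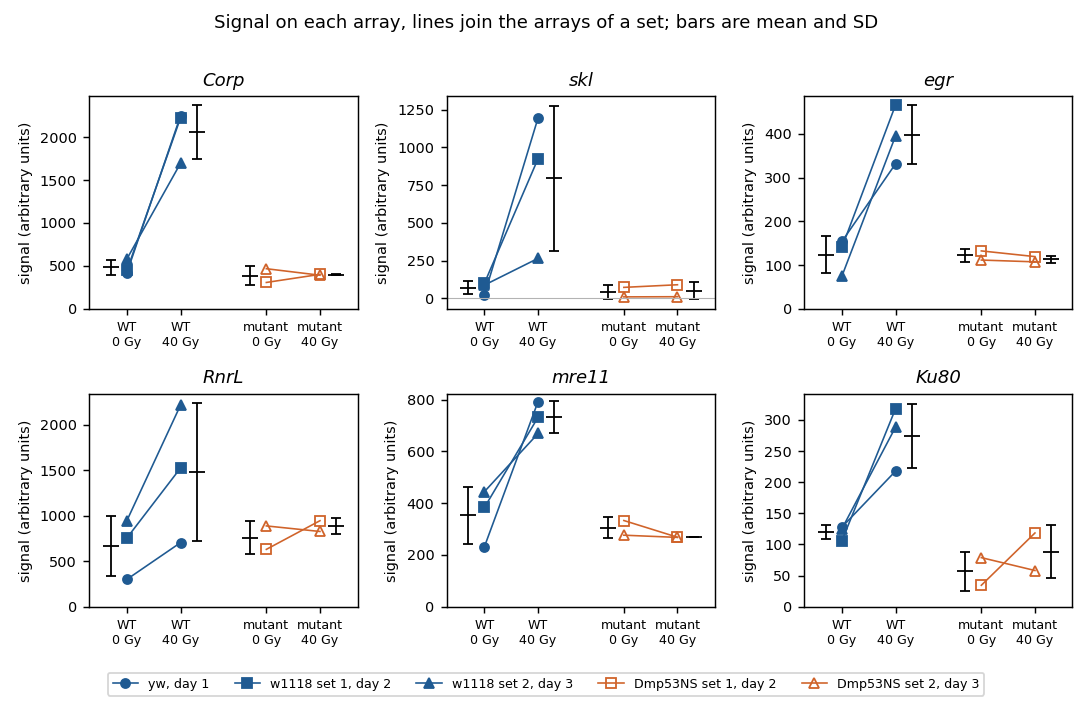
Deposited signal (arbitrary units) of 6 genes of the apoptosis effector, nucleotide supply and DNA repair lists on each of the 10 arrays. Lines join the control (0 Gy) and irradiated (40 Gy) arrays of a set, and bars are the mean and SD of a group. Corp, for example, goes from a mean of 484 to 2057 in WT embryos and from 387 to 397 in the mutant.

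The difference between genotypes in the irradiation effect asked directly which responses depend on p53. The unnamed probe set 141483_at responded more in WT than in mutant embryos, by 4.74 log2 (SE 0.62, adjusted p = 0.00137). Of the genes on the apoptosis effector list, Corp differed by 2.00 log2 (SE 0.38, adjusted p = 0.0839), skl by 2.97 (SE 0.71, adjusted p = 0.361) and egr by 1.71 (SE 0.49, adjusted p = 0.748), and none of these passed. RnrL differed by 0.90 (SE 0.35; 0.56 without the second mutant set) and mre11 by 1.23 (SE 0.41), and neither passed. The Ku genes Irbp and Ku80 differed by 0.27 and 0.55 log2 and did not pass either. The difference of skl was 2.07 without the yw set, and without the second w1118 set both skl (3.82, adjusted p = 0.00747) and Corp (2.26, adjusted p = 0.00747) passed. Limma called only 141483_at; 143680_at (2.41 log2, adjusted p = 0.0558) and Corp also passed at 0.10. Over all probe sets 282 had an unadjusted p under 0.05, against 419 expected by chance. As for the mutant alone, a number under that expected does not show that the other responses are alike. For the 20 probe sets called in WT embryos all 20 differences were positive and 19 had an unadjusted p under 0.05, but those probe sets had been chosen on the WT arrays. In simulated data the same fit recovered 68.6% of differences of 2 log2 and 8.8% of those of 1 log2. The count was 4 with an irradiation term per hybridization day, added after the data were seen. The yw set has no part in that difference, since no mutant set shares its day. The count was 3 without the yw set, 7 without the first and 5 without the second w1118 set, and 3 with a higher pseudocount. It was 0 without either mutant set (345 and 525 unadjusted), with quantile normalization (284), no filter (459), no set block (110) or a random one (169), or without a variance trend (293). The difference of 143680_at passed without the yw (adjusted p = 0.0093), first (0.0259) or second w1118 set (0.0344), and was 3.05 and 1.76 without the first and second mutant set (0.135 and 0.747). Without the yw set the difference of 141483_at was 4.09 log2, and it was 5.44 with a pseudocount of 1 and 3.94 with the higher one. For 141483_at itself the difference was 4.79 log2 without the first and 4.68 without the second mutant set, where its call was lost with 1 mutant set left.

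The 5 groups of genes below differed between genotypes by camera with its preset correlation; with an estimated one camera called 0, fry 0 by its directional and 2 by its mixed test. The published p53 targets had a median difference of 1.07 log2 over 8 genes (camera adjusted p = 1.18e-10, and 0.286 with an estimated correlation). Of them skl, egr, Corp, mre11 and RnrL passed adjusted over the list alone. As above, this list is not independent evidence. The apoptosis, double-strand break repair and checkpoint lists share genes with it and are not fully separate. Apoptosis effectors differed by a median of 0.26 log2 (adjusted p = 0.00686; adjusted p = 0.462 with an estimated correlation), with skl, egr and Corp past the threshold adjusted over the list alone. Double-strand break repair genes differed by 0.35 (adjusted p = 0.0162; adjusted p = 0.539 with an estimated correlation) and checkpoint genes by 0.33 (adjusted p = 0.0425; adjusted p = 0.776 with an estimated correlation). Genes of trachea, salivary gland and epidermis differed by -0.43 (adjusted p = 0.0316; adjusted p = 0.796 with an estimated correlation), with kni (-1.31) past the threshold adjusted over the list alone. On day 2 the median changes of w1118 and mutant embryos were 1.26 and 0.45 for the published targets, 0.37 and 0.26 for apoptosis effectors, 0.24 and 0.16 for double-strand break repair, 0.21 and 0.15 for checkpoint genes, and -0.24 and 0.40 for trachea, salivary gland and epidermis. On day 3 they were 1.17 and -0.07, 0.51 and 0.01, 0.50 and -0.23, 0.05 and -0.11, and -0.44 and -0.22, in the same order. Leaving out 1 set at a time, the published targets stayed at an adjusted p of 9.21e-04 or less. The apoptosis effectors did not pass without the first (0.122) or second mutant set (0.0531). Double-strand break repair did not pass without the first w1118 set (0.0623) or the first (0.0561) or second mutant set (0.110). The checkpoint list did not pass without the yw (0.328), first w1118 (0.130) or second mutant set (0.286) or with quantile normalization (0.0552). The trachea, salivary gland and epidermis list did not pass without the yw (0.128), first w1118 (0.0902), second w1118 (0.0630) or first mutant set (0.613).

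Unirradiated mutant embryos were compared with WT embryos to describe the genotypes before treatment. Of 14 measured transcripts that the mother loads into the egg, 4 passed as higher in the mutant, bcd, smg, pum and swa. The anterior determinant bcd had a mean signal of 1289 ± 497 (n = 2) against 114 ± 25.9 in WT (n = 3; log2 difference 3.43, SE 0.42, adjusted p = 0.00949). The RNA-binding genes smg (3.07 log2) and pum (2.16) and the bcd localization gene swa (2.65) were also higher, as were corolla (4.19), of the synaptonemal complex, the terminal receptor gene tor (4.14), the embryonic linker histone gene BigH1 (3.66) and the meiotic phosphatase gene twe (2.80). Lower in the mutant were ry, the xanthine dehydrogenase gene (signal 3.65 ± 1.20 against 101 ± 31.9; log2 difference -2.68, SE 0.48, adjusted p = 0.0161), and zpg, a germ line gap junction gene (29.2 ± 7.21 against 218 ± 37.8; -2.45, SE 0.38, adjusted p = 0.0117). The mutant signal of ry lies under the pseudocount of 14.5, which sets the size of its difference: it was -4.48 with a pseudocount of 1 and -1.56 with a higher one, past the threshold with both. Of the 14 maternal transcripts 11 had positive differences; adjusted over the list alone 9 were higher and cort (-1.07) was lower, and the median was 1.39 log2 (camera adjusted p = 5.87e-04; adjusted p = 0.680 with an estimated correlation). Against w1118 within days that median was 1.22 on day 2 and 1.43 on day 3. All 13 ribosomal protein genes had negative differences, none of which passed over all probe sets. Their median was -0.51 (camera adjusted p = 0.00249, but adjusted p = 0.840 with an estimated correlation), and it turned to 0.03 with quantile normalization. This did not hold within days, where it was -0.35 on day 2 and 0.03 on day 3 against w1118, and camera's adjusted p without the yw set was 0.524. The other largest differences were tamo (3.46), CG7730 (3.44), CG31674 (3.35), CG3618 (3.33), CG10863 (3.29) and Elba2 (3.26) among higher genes. Lower ones were CG7878 (-2.65), CG14715 (-2.56; a second probe set -0.70, adjusted p = 0.333), CG12885 (-2.50), Tom7 (-2.35), Smyd3 (-2.23), CG12971 (-2.22), Gr21a (-2.21) and CG5089 (-2.14). From the other lists GstE1 (2.31), GstS1 (1.49), Tl (1.32) and dome (0.95; a second probe set -1.51, adjusted p = 0.111) were higher, and GstD5 (-1.91), Cyp6a8 (-1.48), kni (-1.39) and Ance (-1.22) lower. Of the probe sets of Traf4 the brighter gave 0.26 (adjusted p = 0.583) and a second -1.85 (adjusted p = 0.0432). Limma called 549 probe sets, 370 higher and 179 lower. The median of all probe sets was -0.20 log2 (-0.05 with quantile normalization), and it was not subtracted from the differences. Within hybridization days, against w1118 alone (added after the data were seen), 1205 were called and 406 of the 549 were among them. That fit had day terms but no set block, so it treated the control and irradiated arrays of a set as independent. With set as a random block and no day terms, the fit without the yw set called 66. Within days bcd differed by 3.19, corolla by 4.13, tor by 3.83, BigH1 by 3.34, smg by 2.63, ry by -2.71 and zpg by -2.48. The fit without the yw set gave the same differences, and there BigH1 (adjusted p = 0.0657) and smg (0.184) did not pass limma. The control array of the second mutant set had 3′ to 5′ signal ratios of 5.92 (eIF-4a) and 3.52 (actin), against 1.56 to 2.92 and 1.30 to 2.00 on the WT controls. Without the first mutant set, which leaves that set as the only mutant one, limma's count was 0 (1346 unadjusted), and none of the genes named above as past the threshold passed (bcd adjusted p = 0.0982). The count was 177 without the second, 66 without the yw set, 302 without the second w1118 set and 80 on the 5 unirradiated arrays. Of the 32 named calls 19 were lost without the yw set, 5 without the first and 7 without the second w1118 set, and 14 without the second mutant set. Without the first and without the second mutant set the differences were 1.96 and 4.18 for smg, 1.26 and 3.05 for pum, 3.36 and 5.02 for corolla, 3.54 and 4.74 for tor, 1.97 and 3.64 for twe, -1.60 and -3.71 for CG7878 and -1.29 and -2.53 for GstD5. Without the yw set they were 2.74 for tamo, 2.43 for Elba2, 0.89 for GstS1, 0.84 for Tl, 0.50 for dome, -1.51 for Tom7, -1.22 for CG12971 and -1.46 for CG5089, and BigH1 was 3.03 without the first w1118 set. With another pseudocount 14 of the 32 differences moved by over 1.5-fold, and none lost its call: those of ry, zpg, BigH1, corolla, tor, tamo, CG31674, CG3618, CG7878, CG12885, CG12971, CG5089, Tom7 and Gr21a. The p53 genotype, strain background and embryo collection were not separable here.

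**Figure D3:**
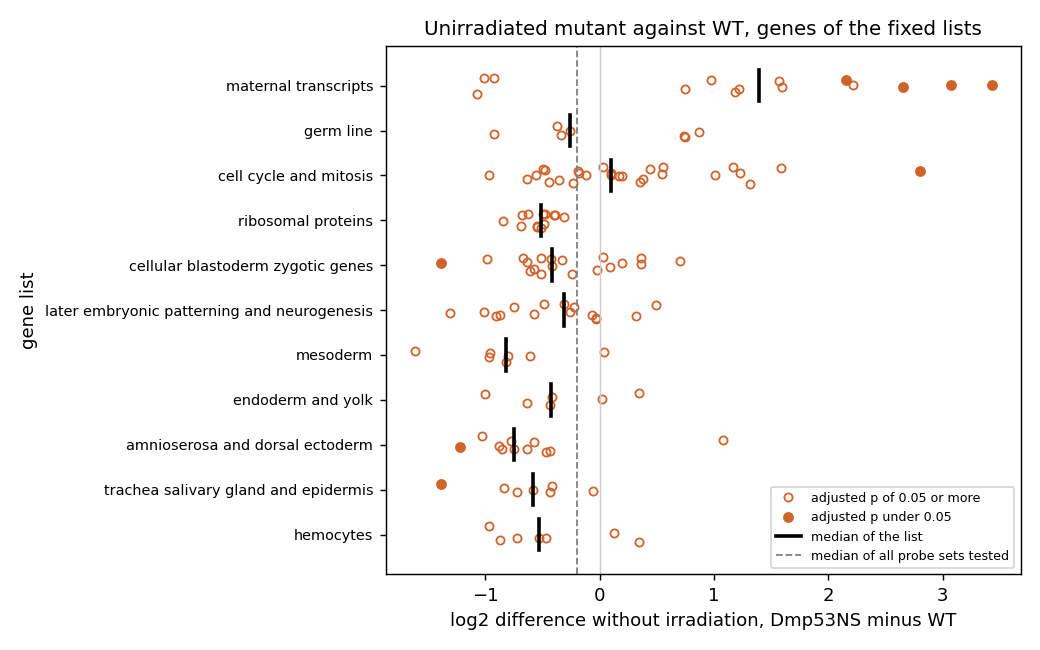
Log2 difference between unirradiated mutant (Dmp53NS) and WT embryos for measured genes of 11 gene lists; each point is a gene, filled where its adjusted p is under 0.05, the bar is the median of the list and the dashed line the median of all 8379 probe sets (-0.20). Maternal transcripts have the highest median (1.39), and with quantile normalization the medians of ribosomal proteins (0.03), germ line (0.09) and cell cycle genes (-0.00396) lie on the other side of 0.

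The yw and w1118 strains were compared as a yardstick of the difference between WT backgrounds, from a single yw set that was hybridized on a day of its own, so that strain and day cannot be told apart. The antimicrobial peptide family gene Drsl5 was higher in yw (6.45 log2, SE 0.55, adjusted p = 6.88e-04), with a control signal of 2292 against 5.3 and 36.4 in w1118. The chemoreceptor gene Ir64a (4.88) and the cytochrome P450 genes Cyp4p2 (4.32) and Cyp4p1 (4.03) were higher as well, followed by CG13794 (4.17), kek1 (3.56), CG13361 (3.35), CG14275 (3.31), CG9119 (2.86) and CG12723 (2.79). CG14111 (-4.06), Tektin-C (-3.41), fend (-3.34), CG8066 (-3.33), CG14985 (-3.18), sktl (-2.59), Marf (-2.55), Cdc27 (-2.53), BTBD9 (-2.52) and Slc25A46a (-2.47) were lower in yw. Of 13 ribosomal protein genes 5 were called as higher (RpL32, RpLP1, RpLP2, RpS15 and RpS18, at 0.93, 1.15, 0.99, 0.87 and 0.88 log2) and 11 were higher adjusted over the list alone. With quantile normalization none of the 5 passed (adjusted p = 0.259 to 0.938), at 0.05, 0.24, 0.24, -0.02 and 0.19 log2 in the same order. The list's median of 0.76 log2 turned to -0.02 with quantile normalization (camera adjusted p = 3.51e-06; adjusted p = 0.593 with an estimated correlation, and 0.823 with quantile normalization). The yw arrays also had the fewest dim probe sets and the strongest 18S rRNA signal. RnrL, one of the radiation-responsive genes, was lower in yw (-1.41 log2, adjusted p = 0.0232), and y, which is mutated in this strain, differed by 0.10 (adjusted p = 0.943). Other list members that passed were scaf (2.15), zen (1.96), DptB (1.47) and Hsc70-3 (1.18) as higher and Keap1 (-2.27), mtrm (-1.98) and Hsc70-4 (-1.02) as lower. The probe sets of 2 genes passed in opposite directions, so that no direction is given: Traf4 (-1.24, and 3.88 with adjusted p = 0.00226) and dome (-1.004, and 2.84 with adjusted p = 0.0226). Limma called 484 probe sets, 251 higher and 233 lower, and with quantile normalization 688, of which 284 were higher. The count was 246 without the second w1118 set, 235 without the first and 180 without the second mutant set, 992 with no set block, 1745 with no filter on dim probe sets, 266 with a stricter one, and 0 on the 5 unirradiated arrays (1283 unadjusted), where yw is 1 array. Of 35 named calls 18 passed without each of the other 4 sets in turn. Without the second w1118 set 12 were lost (adjusted p = 0.0541 to 0.130): dome, Hsc70-3, Marf, RnrL, scaf, Traf4, zen and the ribosomal protein genes. Without the first, DptB, Hsc70-4, mtrm and zen were lost (0.0545 to 0.148). Without the first mutant set 8 were lost (0.0544 to 0.1002), which were dome, DptB, Hsc70-3, mtrm, RpL32, RpS15, RpS18 and zen. Without the second, those 8 and Hsc70-4, Keap1, Marf, RpLP1, sktl and Traf4 were lost (0.0515 to 0.0908). Drsl5 was 5.69 log2 without the first and 7.21 without the second w1118 set. With another pseudocount 15 of the 35 differences moved by over 1.5-fold, such as those of Drsl5 (7.44 with 1, 5.46 with the higher one), Ir64a (6.77, 3.50), Cyp4p1 (5.88, 2.74) and Tektin-C (-4.76, -2.30). Only mtrm (-3.54, and -1.07 with adjusted p = 0.0602), DptB (0.0522 with 1) and zen (0.0601 with 1) lost their call.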

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

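Of the tests in this part, those on selection and hybridization day were chosen after the 20 WT calls and single-gene signals per array had been seen, and the one on uneven 3′ to 5′ signal and the irradiation term per hybridization day only after the result itself was seen. Groups of 2 and 3 arrays are too small for a check of single outlying arrays. The irradiation effect of WT embryos exceeded that of mutant embryos by a tested difference for 141483_at (4.74 log2). For 4 further probe sets every WT set was higher and every mutant set lower after irradiation: 143411_at (1.92), 143721_at (1.74), egr (1.71) and mre11 (1.23). Their differences did not pass limma's test (adjusted p = 0.112 or more), so that a difference is not shown. Camera with its preset correlation, but not with an estimated one, separated the genotypes for apoptosis effectors (median difference 0.26), double-strand break repair (0.35), checkpoint genes (0.33), the published targets (1.07) and, in the other direction, genes of trachea, salivary gland and epidermis (-0.43). The proapoptotic gene grim lay below the filter on dim probe sets; without that filter its WT change was 1.37 log2 (SE 0.49, adjusted p = 0.670 over 13966 probe sets), from a mean signal of 21.1 ± 15.8 to 77.1 ± 41.9 (SD). Its mutant change was -0.21, and the difference of 1.58 did not pass (adjusted p = 0.999).

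The 6 WT arrays were also divided into 2 groups of 3 in every other way, and each split was refitted. The real split gave 20 calls and the highest of the others also 20, so that 3 of the 10 splits reached that number. With set as a block, splits that part the same single pair are the same fit, so that not all 10 are distinct. Even counted as 10, the smallest share is 0.1, which is too few for a share under 0.05. The 2 other splits with 20 calls are the same fit. They part only the yw pair by group and so carry the irradiation change of that set, which had a hybridization day of its own. Splits that part only the second w1118 pair gave 6 calls. Those that part only the first w1118 pair gave 0 with limma (93 unadjusted), as did the other splits that part all 3 pairs (254 to 338 unadjusted, against 683 for the real one). Within sets, the 20 called probe sets had median changes of 2.07 (yw), 1.31 and 1.62 log2 (w1118).

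Probe sets that rose in irradiated WT embryos did not pass as higher in irradiated mutant embryos. Selection on the WT arrays was argued against by choosing the 20 probe sets with the largest rise in the yw set alone: their change in w1118 exceeded that in the mutant by a median of 0.52 log2, above the central 95% of random lists (up to 0.22), while their median in the mutant was 0.11. Hybridization day was argued against, since the same 20 differed by 0.69 on day 2 and 0.68 on day 3, above 0.25 and 0.42 for random lists. All these random lists were matched on mean signal and not on spread. Their ranges may be too narrow for probe sets picked as the largest changes. Among the picked probe sets 141483_at, skl, CG10916, CG12171, Wnk and 143680_at were also called in WT, and the others were not tested apart. The day 2 value also argues against the uneven 3′ to 5′ signal of the second w1118 and second mutant sets, which it leaves out. Loss of p53 is a candidate explanation, as a hypothesis found and tested on the same arrays, while strain background other than p53 and the 2 mutant collections themselves stay open and were not tested, because there was a single mutant strain, and limma called only 1 difference (4 with an irradiation term per hybridization day).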

How the results depend on the processing

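The irradiation term per hybridization day and the comparison of mutant with w1118 within days were added only after the data were seen. The comparison within days had no set block and treated the arrays of a set as independent. Values as deposited, a pseudocount of 1, the robust trend and, for all but the difference, a pseudocount at the 40th percentile left every count of calls within 1.5 times, except that the robust trend gave 2 calls for the difference between genotypes. WT irradiation (20 calls) gave 12 with quantile normalization (11 of the 20), 8 with no filter, 34 with a stricter filter, 3 without a variance trend, 11 with WT arrays alone, 99 by a 1.5-fold rule with no test (80 higher, 19 lower, 18 of the 20), and 12 to 41 with 1 set left out. With no replicate block it gave 5 and with a random replicate block 6. Mutant irradiation (0 calls by limma, 134 unadjusted) gave 1 with mutant arrays alone, 160 by the 1.5-fold rule and 0 to 3 with 1 set left out. The difference between genotypes (1 call) gave 0 with quantile normalization, no filter, no variance trend, no replicate block or a random replicate block (limma, 110 to 459 unadjusted). It gave 3 with the higher pseudocount or at 0.10, 7 with the stricter filter, 117 by the 1.5-fold rule, 4 with the term per day, and 0 to 7 with 1 set left out. Mutant against WT (549) gave 1345 at 0.10, 80 on the 5 unirradiated arrays, 1205 within days and 0 to 374 with 1 set left out. There, and for mutant irradiation, the block moved no count by more than 1.5 times. The comparison of yw with w1118 (484) gave 1745 with no filter, 266 with the stricter one, 1098 at 0.10, 992 with no replicate block, 0 on the 5 unirradiated arrays (limma, 1283 unadjusted) and 180 to 488 with 1 set left out. Leaving out the only yw set gave no value. Of the lists, camera called 6 for WT irradiation, 2 for mutant irradiation, 5 for the difference, 2 for mutant against WT and 1 for yw against w1118, and 0 for each with an estimated correlation. Directional fry called 2, 0, 0, 6 and 5, and mixed fry 8, 0, 2, 14 and 18, in that order. Quantile normalization left 1 list for mutant against WT and 0 for yw against w1118, and with 1 set left out camera called 3 to 7, 0 to 5, 2 to 4, 1 to 3 and 1 to 3. Fewer arrays, fewer residual degrees of freedom or more probe sets tested are part of the left-out, single-genotype and unfiltered settings by construction. Otherwise the cause was not tested. Among named genes, 111 of the values under an alternative lost their call and 1 gained one for WT irradiation. The counts were 7 and 21 for the difference, and 115 lost it for mutant against WT and 96 for yw against w1118. Of values that passed in either setting, RpS15 alone changed sign, while some that passed in neither did so too, such as Ku80 for the difference (0.55, range -0.35 to 1.46). RpS15 was 0.87 log2 in yw against w1118 and -0.017 with quantile normalization, where the cause was not tested. Dim probe sets limit all of this: a signal near the pseudocount of 14.5 shows only part of its fold change.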

Other observations

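Of the tests in this part, those on the hybridization day of the maternal list and on the array-wide difference in low signals were chosen after the pooled maternal median and the correlation between the mutant sets had been seen, and those on blastoderm-stage embryos, on unfertilized or arrested eggs, on strain background and on unequal developmental progress only after the result itself was seen. In irradiated WT embryos the transcription factor gene kni, of gap and tracheal patterning, was lower in all 3 sets (-1.53, -0.89 and -0.80 log2) and 0.46 and 0.02 in the mutant sets. Over all probe sets its adjusted p was 0.152. The glutathione transferase genes GstD5 (1.29 log2, adjusted p = 0.154) and GstE6 (1.21, adjusted p = 0.164) were higher in all 3 WT sets. The mutant sets gave 0.95 and 0.17 for GstD5 and 0.02 and 0.58 for GstE6. The translesion polymerase gene PolZ1 (1.35 log2) and rad50 (1.23) each had an adjusted p of 0.0706 in WT. In unirradiated mutant embryos mesoderm genes had a median of -0.82 log2 and amnioserosa and dorsal ectoderm genes one of -0.75. The 4 JAK-STAT genes, all with positive differences, had one of 0.88. None of the 3 lists passed camera (adjusted p = 0.0794 for each, and 0.680 or more with an estimated correlation), but mesoderm did without the first mutant set (0.0412). Directional fry, which does not compare a list with other genes, passed all 3 (adjusted p = 0.0470, 0.0482 and 0.0298). Adjusted over their lists alone, sna (-0.82), bap (-0.96), Doc1 (-1.03) and Ance (-1.22) were lower, and 3 JAK-STAT genes higher: dome (0.95; a second probe set -1.51), Stat92E (1.10) and Ptp61F (0.81). All 6 genes of adult ovary or chorion had positive differences in yw against w1118, with a median of 0.75 (camera adjusted p = 0.129, directional fry 0.0194). None passed over all probe sets, while Yp3 (1.63), Cp18 (0.85) and Vm26Aa (1.15) passed when adjusted over the list alone.

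The maternal list had a median of 1.39 log2 in unirradiated mutant against WT embryos, with 4 of 14 genes past the threshold, none of them without the first mutant set, and no call of the list with an estimated correlation (adjusted p = 0.680). Hybridization day was argued against, since the median against w1118 was 1.22 on day 2 and 1.43 on day 3, above the central 95% of random lists (up to 0.32 and 0.35), with 11 of 14 genes higher on each day. More unfertilized or arrested eggs in the mutant collections may account for it: 65 zygotic genes together had a median of -0.53, below the central 95% of random lists (down to -0.40), with 52 lower. More embryos at the cellular blastoderm stage, or another developmental delay, stays open, since blastoderm genes had a median of -0.41, inside the central 95% of random lists (-0.55 to 0.38) with 6 of 19 higher, and slower decay of maternal RNA was not tested. A strain background other than p53 cannot be told apart from the genotype with 1 mutant strain, and between yw and w1118 the list differed by -0.28.

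The changes of the mutant sets after irradiation ran against each other, with a correlation across probe sets of -0.29 (probe sets are not independent replicates). An array-wide difference in low signals was argued against, since the correlation stayed at -0.26 after quantile normalization. Control and irradiated mutant collections of unequal developmental progress may account for it: zygotic genes had a median of 0.29 in the first mutant set, where maternal transcripts had -0.49, and of -0.33 in the second, where maternal transcripts had 0.46, all outside the central 95% of random lists. In WT sets the zygotic median was also outside that range in yw (-0.28), and the maternal one in the first w1118 set (0.41). The eIF-4a 3′ to 5′ signal ratio was 5.92 on the control and 3.13 on the irradiated array of the second mutant set. In the first mutant set it was 2.11 and 2.14. Whether this uneven signal has a part in the opposed changes was not tested. Nor was any explanation by genotype or irradiation tested for them.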
